A study of Mus musculus with 5 samples.

How the data were processed

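The series holds RNA-seq of keratinocytes sorted from mouse skin wounds 5 days after wounding, in 2 Nrf2 conditional knockout (cKO) samples, numbered 2 and 3, and 3 wild-type (WT) littermate samples, numbered 1 to 3. Per the labels' protocols, tissue around the wound was dissociated, lineage-positive and dead cells were depleted, and live cells positive for CD49f and negative for a lineage antibody mix (CD5, CD45R, CD11b, Cr-1, 7-4 and Ter-119) were sorted. That mix is directed at blood cells and holds no antibody against endothelial cells, fibroblasts or melanocytes. The labels' protocols describe amplified cDNA libraries made from total RNA with a Nugen Trio kit and paired-end reads from an Illumina HiSeq sequencer. Trimmomatic 0.35, STAR 2.6.0c, RSEM and the mouse build mm10 are named, per the submitters' processing notes. Whether the samples came from separate animals is not stated in the labels, so any spread behind the deposited p-values may be technical. Among 1373 genes at 16 CPM or more with an absolute log2 fold change of 0.5 to 3, p-values of genes of like fold and level were nearly the same, so there they do not measure each gene's own spread between samples. Lower genes, which most calls are, were not covered by that check.

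The values analysed are the authors' own comparison of the genotypes, 1 entry for each of 10664 genes, and no value per sample was analysed here. The authors gave for each gene a log2 fold change, a mean level in log2 CPM, a p-value and a false discovery rate (FDR), per the file headers. The title of the authors' deposited table speaks of TPM, a filter, a pseudocount and protein-coding, miRNA and lncRNA genes, and the tool behind the fold changes and p-values is not given in the sources used here. Nor is it stated there which of the 5 libraries entered the comparison. The base of the level was taken as 2 because 2 to the power of the deposited level summed to 1.00436e+06 over all genes. The deposited FDR was recomputed from the deposited p-value by the Benjamini-Hochberg method, with a largest difference of 7.17e-15. A second sheet from the authors held 278 genes with deposited log2 values and p-values, which matched the genes with an FDR under 0.05 with a largest difference of 0. Text notes beside 2 negative entries of that sheet describe them as higher in the knockout, so positive deposited values were read as higher in WT. All fold changes below were turned round to log2 of cKO relative to WT.

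The design fixed before the data were examined was limma on log2(TPM + 1) with camera for gene lists, and the fixed rule for named genes needed values per sample. None of these could be run on a comparison table. The authors' FDR under 0.05 was used in place of the fit, for calls over all genes. Gene lists were tested with cameraPR of limma 3.58.1 in R 4.3.3, two-sided, on signed z values made from the deposited p-values, with a preset correlation of 0.01 between genes and Benjamini-Hochberg adjustment over the lists with at least 3 analysed members. This substitute was chosen after the contents of the table were seen. A correlation cannot be estimated from these values, so a preset correlation of 0.05 was run as an alternative. Members passing when adjusted over the list alone were counted as well. Members of a list counted below as lower or higher are those past the threshold, unless the text speaks of values. Tables and plots were made with Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.

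The list test was tested on simulated data for the 10664 genes of this comparison. In the first simulated draw, 5 of 5 shifted lists were recovered and 2 of 23 unshifted lists were also called, of which 1 shared a gene with a shifted list. A repeat over 100 draws, added after that result was seen, recovered 99.6% of the shifted lists, each shifted by 1.5 in z, and called 0.944% of 2118 unshifted lists that shared no gene with a shifted one. These draws had independent genes, so they do not cover correlation between genes.

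Symbols, positions and gene types came from GENCODE vM21, which uses the same build, and 10655 of the 10664 genes had a position there. Named genes were, by the rule fixed before the data were examined, Nfe2l2, the 10 called genes with the largest fold change in each direction, up to 4 members per list with the smallest p, and Ccl2, Egf, Egfr and Nqo1. The condition that samples of the genotypes be separated could not be applied. Egf was not analysed here. A further result that the rule would name is not reported here. The other named genes were chosen after their values were seen: genes away from the floor, sex-linked genes, keratins, myelin genes, and well-known members of a list, such as Mki67 and mt-Co1, given beside its called genes. Not every gene that the rule takes is named in the text. A gene was called near the floor where its implied level in 1 genotype was under 0.05 CPM, assuming that both genotypes weigh alike in the mean level. That limit was chosen after the data were seen. The fold change of such a gene depends on the pseudocount or prior the authors used, so its mean level and adjusted p are given instead. Depth per sample is unknown here, and no SD, standard error or n can be given for single genes.

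The 31 fixed lists were: the targeted gene and its repressor; NRF2 targets in 4 lists (glutathione and thioredoxin, quinone, carbonyl and drug metabolism, heme and iron, NADPH and pentose phosphate); chemokines; cytokines; the EGF family; growth factors of repair; proliferation; basal, differentiated and wound-activated keratinocyte genes; hair follicle and sebaceous genes; interferon response; glycolysis and hypoxia; cholesterol synthesis; unfolded protein response; nuclear oxidative phosphorylation; mitochondrially encoded genes; ribosomal proteins; dissociation response; and markers of fibroblasts, macrophages and dendritic cells, neutrophils, lymphocytes, endothelium, pericytes and muscle, melanocytes and Schwann cells, erythroid cells and adipocytes. Alternatives were a fold threshold (planned), and, added after the data were seen, a level filter of 5 CPM, a stricter threshold of 0.01, near-floor genes left out, another adjustment, an empirical null, and other statistics for the lists.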

Results

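Gene expression was compared between keratinocytes sorted from wounds of mice lacking Nrf2 in keratin 14-expressing cells (2 cKO samples) and of WT littermates (3 samples), 5 days after wounding. Nrf2, encoded by Nfe2l2, is a transcription factor that switches on antioxidant and detoxifying genes. The series asks which genes it regulates in keratinocytes during repair, and its title names the chemokine Ccl2 and EGF. All values are from 1 comparison made by the authors, and no spread between samples can be given for a single gene.

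Markers of blood vessels and fibroblasts, chemokines, cytokines and wound-activated keratinocyte genes were lower in cKO as lists. The cytokine list did not pass the list test with near-floor genes left out (adjusted p = 0.277). Nor did the chemokine list with a level filter of 5 CPM (adjusted p = 0.0838). Among 52 analysed NRF2 target genes 1, Gpx2, passed the test, at a mean level of 1.44 CPM. The smallest called change of any gene was 2.20, so smaller falls of these targets stay undecided. In the authors' deposited table, 278 of 10664 genes passed an adjusted p of 0.05, of which 229 were lower and 49 higher in cKO. Ccl2, which attracts monocytes, fell by 3.01 on the log2 scale (adjusted p = 0.0256 in the authors' deposited table). Dsc2, a desmosomal cadherin, rose by 4.15 at a mean level of 145 CPM, and Krt2, a keratin of late epidermal differentiation, rose by 4.02, per the authors' deposited table.

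The targeted gene Nfe2l2 (ENSMUSG00000015839, chromosome 2, 75675513 to 75704641, minus strand, mm10) had a log2 fold change of -1.99 at a mean level of 189 CPM, and missed the threshold with adjusted p = 0.126 in the authors' deposited table. Its value in each sample was not analysed here, and the deleted part of the gene is not given in the sources used here. Keap1, which marks NRF2 for degradation, had a value of -0.79 in the authors' deposited table. This list of 2 genes was too small to test, and 1 of them, Nfe2l2, passed as lower when adjusted over the list alone.

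Across the 4 lists of NRF2 targets, 33 genes had lower and 19 higher values in cKO, with a median of -0.09, and none of the lists passed. In the glutathione and thioredoxin list, 14 of 21 analysed genes had lower and 7 higher values (list adjusted p = 0.362). Of these genes 1 was called lower, and 3 were lower and 1 higher when adjusted over the list alone. Gpx2, a glutathione peroxidase, fell by 4.69 at a mean level of 1.44 CPM (adjusted p = 0.0114 in the authors' deposited table). At that level it was removed by the alternative filter of 5 CPM. The cystine transporter gene Slc7a11 had a value of -2.93 (adjusted p = 0.0545), glutathione reductase Gsr -2.18 and the glutathione transferase Gsta1 1.68, per the authors' deposited table. These calls moved both ways with the setting. Gpx2 was lost under the Benjamini-Yekutieli adjustment (adjusted p = 0.113), while Slc7a11 and Gsr passed under the empirical null (adjusted p = 0.00369 and 0.0123). Of 17 genes of quinone, carbonyl and drug metabolism, 0 passed (list adjusted p = 0.251), and 1 was lower when adjusted over the list alone. Adh7 had -2.15, Akr1b8 -1.84, Abcc3 -1.80 and Nqo1, a classical NRF2 target, 1.33 with adjusted p = 0.720 in the authors' deposited table. None of the 7 heme and iron genes passed (list adjusted p = 0.912), and their median of -0.03 and the list test differed in sign. The authors' deposited table gave Ftl1, the ferritin light chain, -1.67 and Blvrb 1.18. None of the 7 NADPH and pentose phosphate genes passed (list adjusted p = 0.992).

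Chemokines were lower as a list (median -1.10, adjusted p = 8.49e-05), with 5 of 15 analysed members lower and 1 higher, or 6 and 1 when adjusted over the list alone. Besides Ccl2 (ENSMUSG00000035385, chromosome 11, 82035571 to 82037453, plus strand, mm10), the neutrophil attractants Cxcl5 and Cxcl2 fell by 4.35 and 3.61, per the authors' deposited table. Cxcl3 and Ccl11 were lower and near the floor in cKO, at mean levels of 2.26 and 0.934 CPM in the authors' deposited table (adjusted p = 0.000323 and 0.0435). Cxcl9, an interferon-induced chemokine, rose by 2.23 (adjusted p = 0.0310 in the authors' deposited table). Cytokines and colony-stimulating factors were lower as a list (median -0.91, adjusted p = 0.000300), with 3 of 17 lower, or 4 lower and 1 higher when adjusted over the list alone. Il6 fell by 2.81 (adjusted p = 0.0199), and Il24 and Lif were lower and near the floor in cKO, at mean levels of 5.80 and 1.32 CPM in the authors' deposited table. With near-floor genes left out, the cytokine list had adjusted p = 0.277, and with a level filter of 5 CPM the chemokine list had adjusted p = 0.0838. Endothelial and fibroblast markers were lower in the same comparison, with medians of -3.49 and -2.67.

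In the EGF family, 9 of 12 genes had lower and 3 higher values, and the list did not pass (median -0.45, adjusted p = 0.151). Of these genes 1 was called lower, also when adjusted over the list alone. That gene was Btc (chromosome 5, 91357261 to 91402994, minus strand, mm10), the EGF receptor ligand betacellulin. It fell by 3.22 at a mean level of 3.61 CPM (adjusted p = 0.00914 in the authors' deposited table), and was removed by the alternative filter of 5 CPM. The receptor gene Egfr had a value of 0.20 at 533 CPM, and the ligand genes Ereg and Nrg1 had -1.08 and -0.93 in the authors' deposited table. Of 10 growth factors of repair, 0 passed (adjusted p = 0.795), and Fgf1 had -0.98 in the authors' deposited table.

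Wound-activated keratinocyte genes were lower as a list (median -1.08, adjusted p = 3.89e-08), with 6 of 29 lower, or 10 when adjusted over the list alone. The authors' deposited table showed falls in the matrix metalloproteinase genes Mmp9, by 4.83, and Mmp13, by 3.94. The activin subunit gene Inhba fell by 4.55, per the authors' deposited table. The wound keratins Krt6a, Krt6b, Krt16 and Krt17 had values of -1.25, -1.76, 0.08 and -0.48, each with an adjusted p over 0.05 in the authors' deposited table. Several of the genes that fell are also made by fibroblasts or myeloid cells, and fibroblast markers had a median of -2.67. Proliferation genes were lower as a list (median -0.53, adjusted p = 0.00385, and adjusted p = 0.0666 with a preset correlation of 0.05). Of its 35 members 31 had lower and 4 higher values, and 1 was called. That gene, Birc5, which encodes survivin, fell by 2.96 in the authors' deposited table. It was also the 1 gene that passed when adjusted over the list alone. Kif20a had -1.82 and Mki67 -0.17 in the authors' deposited table.

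Basal keratinocyte genes did not pass as a list (median -0.39, adjusted p = 0.476), with 0 of 17 called. Krt5 had 0.10 and Krt14 -0.24 in the authors' deposited table. Differentiated keratinocyte genes had 1 of 23 higher, Krt2, also when adjusted over the list alone, and adjusted p = 0.931, with a median of -0.18 that differed in sign from the list test. Krt1 and Krt10 had 0.27 and 0.36 in the authors' deposited table. Hair follicle and sebaceous genes were lower as a list (median -0.49, adjusted p = 6.41e-05), with 2 of 18 lower, or 6 when adjusted over the list alone. In the same comparison endothelial and fibroblast markers had medians of -3.49 and -2.67. Elovl3, a fatty acid elongase, fell by 2.76, and Scd3, a sebaceous desaturase, was lower and near the floor in cKO at 5.79 CPM in the authors' deposited table.

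**Figure D1:**
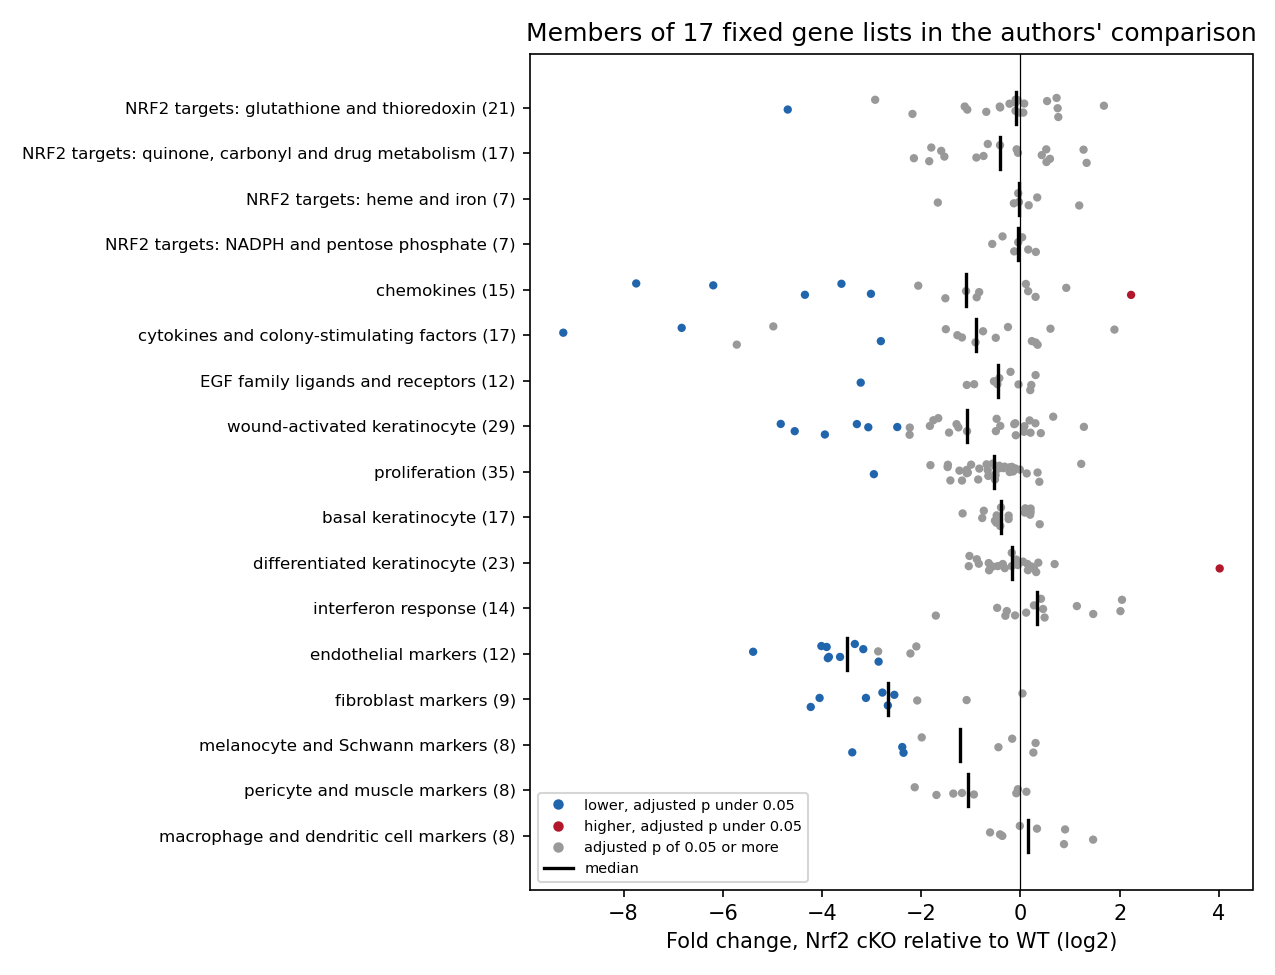
Log2 fold change of cKO relative to WT (horizontal axis) for each analysed member of 17 fixed gene lists, with the number of members in brackets, a bar at each list's median, and color by the authors' adjusted p (blue lower, red higher, gray not past 0.05). Endothelial and fibroblast markers lie lowest, with medians of -3.49 and -2.67, while the medians of the 4 NRF2 target lists lie between -0.41 and -0.03, and points near the floor carry folds that depend on the authors' pseudocount or prior.

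Endothelial markers had the largest shift of the 28 lists tested, with 9 of 12 lower, or 12 when adjusted over the list alone (adjusted p = 6.65e-26). Flt1 and Cdh5, the VEGF receptor and VE-cadherin genes, fell by 5.39 and 4.01, per the authors' deposited table. Fibroblast markers had 6 of 9 lower, or 7 when adjusted over the list alone (adjusted p = 8.52e-15). The collagen gene Col3a1 fell by 4.05 at 196 CPM and the proteoglycan gene Dcn fell by 4.23, per the authors' deposited table. Melanocyte and Schwann markers had 3 of 8 lower, or 4 when adjusted over the list alone (median -1.22, adjusted p = 0.00198, and adjusted p = 0.0702 on ranks). The pigment genes Dct, Mlana and Tyrp1 fell by 2.38, 3.39 and 2.36, while the myelin genes Mbp and Pmp22 had 0.26 and -0.17, per the authors' deposited table. Pericyte and muscle markers were lower as a list with 0 of 8 called, or 1 lower when adjusted over the list alone (median -1.06, adjusted p = 0.0224, and adjusted p = 0.0585 with a preset correlation of 0.05). Mcam had -2.13 in the authors' deposited table.

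Among blood cell markers, those of macrophages and dendritic cells had 0 of 8 called (median 0.16, adjusted p = 0.373), and Cd68 had 1.46 in the authors' deposited table. Neutrophil markers had 1 of 5 lower, also when adjusted over the list alone (median -0.54, adjusted p = 0.134, and adjusted p = 0.0451 with a level filter of 5 CPM), and that gene was Stfa2, which fell by 2.63 in the authors' deposited table. The 1 analysed lymphocyte marker, Thy1, had -1.09, and the erythroid genes Hba-a1 and Hba-a2 had 0.90 and 1.26 in the authors' deposited table, with too few members to test. Of 4 adipocyte markers 0 were called (median -0.66, adjusted p = 0.895).

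Interferon response genes were higher as a list (median 0.34, adjusted p = 0.0433), with 0 of 14 called and 2 higher when adjusted over the list alone. They did not pass as a list with a preset correlation of 0.05 (adjusted p = 0.124), on ranks (0.141) or on log2 fold changes (0.163). Gbp2 and Oasl2 had 2.05 and 2.01 in the authors' deposited table. Mitochondrially encoded genes were higher as a list (median 0.16, adjusted p = 0.0472), with 1 of 13 higher, also when adjusted over the list alone. That gene, mt-Nd3, a subunit of respiratory complex I, rose by 3.43, while the others lay between 0.05 (mt-Co1) and 0.40 (mt-Nd4l) in the authors' deposited table. This list did not pass with a preset correlation of 0.05 (adjusted p = 0.124), on ranks (0.0754) or on log2 fold changes (0.141). Not past the threshold as lists, with 0 genes called in each, were glycolysis and hypoxia (23 genes, adjusted p = 0.209), cholesterol synthesis (22 genes, 0.202), nuclear oxidative phosphorylation (30 genes, 0.476), ribosomal proteins (35 genes, 0.311) and the dissociation response (24 genes, 0.0831, and adjusted p = 0.0104 on ranks). The unfolded protein response list of 20 genes did not pass either (adjusted p = 0.992), and its median of -0.01 differed in sign from its test.

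By size of change, 9 of the 10 most lowered genes were near the floor in cKO, among them Cyp2f2, Apod, Selp and Ccl21a, with mean levels of 7.83, 6.18, 5.99 and 5.39 CPM in the authors' deposited table. Ddx3y, on the Y chromosome, was the exception and fell by 9.51 at 35.3 CPM (adjusted p = 1.71e-11 in the authors' deposited table). The X-linked RNA gene Xist rose by 2.58 (adjusted p = 0.00557 in the authors' deposited table), and Jpx, an X-linked RNA gene beside it, rose by 2.57 (adjusted p = 0.0275). The sex of the animals is not given in the sources used here. These sex-linked changes may therefore come from more female mice among the cKO samples and not from the genotype. Away from the floor, and chosen after their values were seen, Dab2, Slit2 and the osteopontin gene Spp1 fell by 6.37, 6.35 and 5.85, per the authors' deposited table. Among the 10 most raised genes, Hamp, Adgrg7 and AU018091 were near the floor in WT, and 3 others were unnamed gene models. Thumpd2 rose by 6.53 at a mean level of 2.42 CPM and Cd27 by 4.82 at 0.931 CPM in the authors' deposited table. At such low levels these folds may also depend on the pseudocount or prior.

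**Figure D2:**
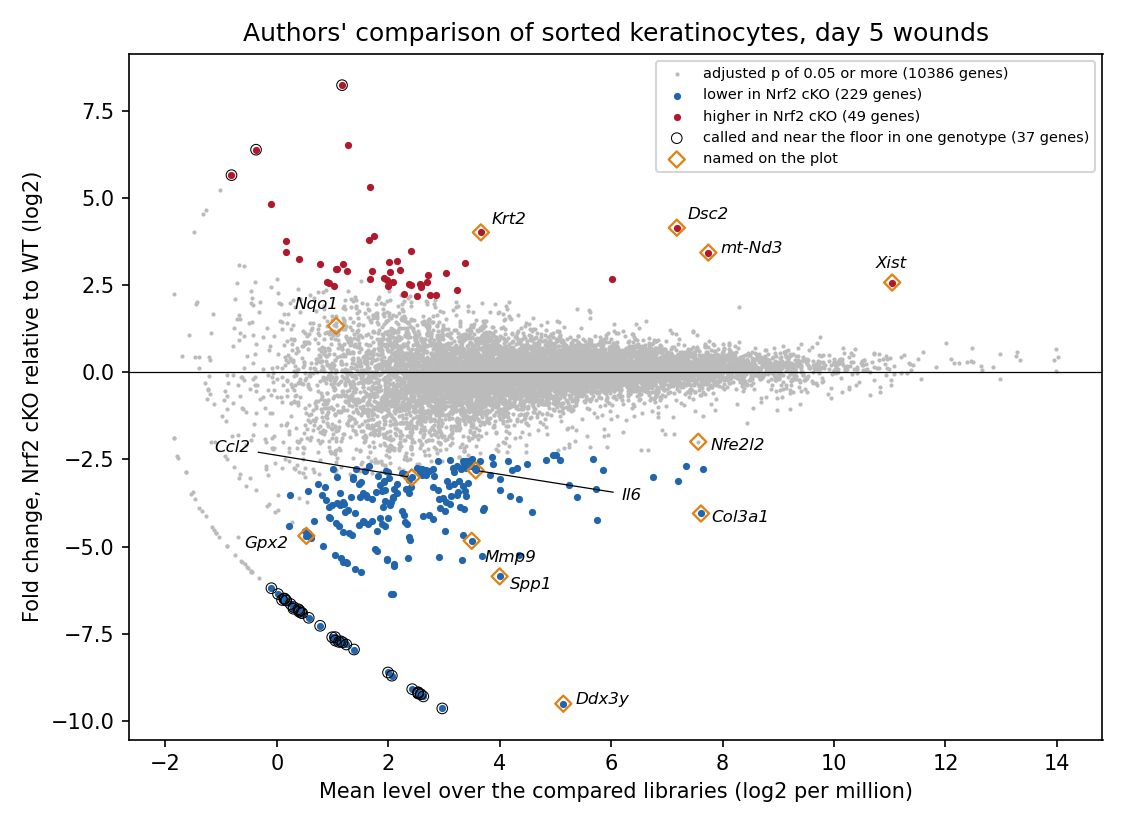
Log2 fold change of cKO relative to WT (vertical axis) against the authors' mean level (log2 CPM, horizontal axis), 1 point per gene, colored by the authors' adjusted p, with black rings on called genes near the floor in 1 genotype and orange diamonds on genes named on the plot. The 229 lower genes outnumber the 49 higher ones, and the 34 ringed genes among the lower ones follow a nearly straight edge.

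The implied standard error of the fold changes varied by a median of 0.437% among genes of like fold and level. This covered 1373 genes at 16 CPM or more with absolute log2 fold changes of 0.5 to 3. In that range p-values followed fold and level almost alone, and the lower genes that make up most calls were not covered. The same measure was 9.21% in simulated data with a spread estimated for each gene and drawn toward a common value (3 residual and 10 prior degrees of freedom). Those settings were assumed, and a stronger pull toward the common value would give a smaller figure. A level filter of 5 CPM, chosen after the data were seen, left 104 calls, and the Benjamini-Yekutieli adjustment left 116 and ended the calls of Ccl2 (adjusted p = 0.252), Btc (0.0901), Gpx2 (0.113), Il6 (0.196), Birc5 (0.184), Cxcl9 (0.306) and Xist (0.0549).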

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

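All alternatives here were chosen after the data were seen, except the fold threshold of 1 on the log2 scale, which kept all 278 calls (229 lower, 49 higher) because the smallest called change was 2.20. A level filter of 5 CPM left 104 calls (88 lower, 16 higher), a threshold of 0.01 left 152 (125 and 27) and the Benjamini-Yekutieli adjustment left 116 (98 and 18), all among the 278. An empirical null, with z divided by its robust SD of 0.821, gave 560 (426 and 134), including the 278. Leaving out near-floor genes gave 235, and leaving out markers of other cell types and genes on X and Y gave 250. The short marker lists held only 19 of the lower calls, so the 250 cannot tell how many calls came from other cells. Stricter thresholds and adjustments lower counts by construction, and the empirical null raises them because dividing by 0.821 enlarges z. The level filter removed many called genes outright, since their median mean levels, 4.32 CPM (lower) and 4.03 CPM (higher), lay under 5 CPM. How many more were lost on readjustment was not counted. With a preset correlation of 0.05, 7 of the 11 called lists passed; other settings gave 8 to 12, and lists gained were dissociation (adjusted p = 0.0175 with the level filter, 0.0104 on ranks) and neutrophil markers (0.0451 with the level filter). Of 87 adjusted p-values followed for 13 genes, 71 stayed on their side of the threshold, 13 were lost and 3 gained. Values under the fold threshold could not move, since it left each adjusted p as it was. Genes not called could not be gained under the threshold of 0.01 or the Benjamini-Yekutieli adjustment. The 71 therefore overstates how stable the calls were. Among these alternatives, Nfe2l2, Slc7a11 and Gsr passed under the empirical null alone (adjusted p = 0.0146, 0.00369 and 0.0123). Slc7a11, Gpx2 and Btc were not among the genes kept by the level filter. Adjustment over a list alone, under which Nfe2l2 passed, is not among these alternatives. Nfe2l2 ranged from 0.0146 to 1 over them, and Ccl2 from 0.00111 to 0.252. Cxcl9 was also lost with the level filter (adjusted p = 0.0577). No paired analysis was possible because the authors' comparison carries no value per sample. For the same reason the other pseudocount, no filter, both rescalings, leaving out each replicate, library weights, the other eBayes settings, an estimated correlation, fry and the check of an own fit against the authors' genes were not run. Depth per sample is unknown here, so its effect on low genes could not be separated.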

Other observations

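The tests in this part were chosen after the values they concern were seen, except that the bounds of the tests over length and GC deciles were set before those tests were run; the decile tests were themselves added after the first length test had left the question open.

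Of 21 endothelial and fibroblast markers 71.4% were called lower in cKO, including 7 of the 10 most abundant, against 37.5% of the 8 melanocyte and Schwann markers, where the 3 called are pigment genes and the source stays open. A candidate explanation is that more endothelial cells and fibroblasts were in the WT libraries, since the lineage mix is not directed at them. However, the sort also required CD49f, which fibroblasts carry little of, and that objection covers fibroblasts and not endothelial cells. The test also rests on the values in which the pattern was seen, and a genotype effect on these cells or genes was not tested. Whether a uniformly lower keratinocyte share in WT accounts for the pattern stays open. Pericyte and muscle markers, also outside the gate, had a median 2.43 above that of endothelial markers with the middle ranges apart (-1.44 to -0.08 against -3.89 to -2.87). That list was itself lower in the list test (adjusted p = 0.0224). It also mixes cell types and holds Notch3 (-0.05), a member of the differentiated keratinocyte list as well, so its median cannot decide. Whether Ccl2 fell because such cells were fewer stays open, because 11 of 21 endothelial and fibroblast markers fell by more than Ccl2 and no value per sample separates the sources. Macrophage and dendritic cell markers, the first choice for the test of keratinocyte share and set aside because the gate is directed at such cells, had a median 3.65 above the endothelial one.

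Ddx3y was lower and Xist higher in cKO, the latter by 2.58. More female mice among the cKO than the WT samples may account for this, but it stays open because the sex of the animals is not given in the sources used here. If so, sex and genotype cannot be told apart in these values. The other of the 2 analysed genes on Y, an unnamed gene model, had 2.03 (adjusted p = 0.0747). Whether that gene is specific to males was not examined, so it was not weighed for or against. Whether X-linked dosage added calls stays open: 8 of 326 genes on X were called (2.45%, exact 95% interval 1.07% to 4.78%) against 268 of 10327 genes placed outside X and Y (Fisher's exact test, two-sided, p = 1). Of 5 protein-coding genes known to escape X inactivation, 0 passed the authors' FDR (median 0.10), while Jpx, an RNA gene that also escapes it, rose by 2.57. The smallest called change of any gene was 2.20, so a change of 1 on the log2 scale, as from a second X copy, was not called anywhere. Neither count can therefore tell whether X-linked dosage or sex differed. Under the Benjamini-Yekutieli adjustment Xist was no longer called (adjusted p = 0.0549).

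Of the called genes, 82.4% were lower in cKO. Near-floor genes alone could not account for this, since 80.9% were lower with them left out. Transcript length and GC content stay open: 61.4% of lowered genes were longer (exact 95% interval 54.8% to 67.8%) and 42.1% had more GC (35.6% to 48.8%) than the median of genes of like level. In the added test no length decile had a median beyond 0.0694 in size and no GC decile beyond 0.135, which argues against a shift common to all genes of a length or GC content. A genotype effect may remain, and was not tested apart from the mixture of cells described above.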
